A study of Mus musculus with 9 samples.

How the data were processed

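Polyadenylated RNA was sequenced from 9 samples of mouse small intestinal organoids, which are epithelial structures grown from intestinal stem cells. The organoids came from a mouse that expresses Cas9 and carried CRISPR edits in Apc and Trp53 and the G12D form of Kras, per the labels' protocols. They were infected with 1 of 3 short hairpin constructs, shNTC, shUsp10-1 or shUsp10-2, and each group had 3 libraries. The labels do not say whether the 3 replicates of a group were grown or infected separately, so p-values measure only the spread between these samples, which may be technical. Libraries were made with a directional kit, per the labels' protocols, and the strand setting used in counting is not given in the sources used here.

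The deposited values were CPM (reads of a gene per 1000000 reads of its library) for 17399 genes in 2 tables, which set shNTC beside each hairpin. The labels call the values normalised, and the values of each library summed to 1000000 over the listed genes. The submitters' processing notes name Bowtie2 2.4.1, featureCounts, edgeR and the mouse build mm10, without versions for featureCounts and edgeR and without the order of steps. Every value was a whole multiple of the value of 1 read in its library, so that whole reads could be recovered for 100% of values within 0.001 read. The lowest total of a listed gene was 9 reads over the 9 libraries. None of the 13 mitochondrial genome transcripts looked for was listed. The 3 shNTC columns were identical in both tables, so the hairpins lay on 1 scale and could also be compared with each other.

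Recovered reads were 20832066, 21450583 and 6511100 in shNTC replicates 1, 2 and 3. They were 6940456, 6321055 and 6265591 in shUsp10-1 and 4972335, 7496338 and 5364009 in shUsp10-2. The deepest library had 4.31 times the reads of the shallowest. A gene at 10 CPM had 49.7 to 215 reads per library, which gives a counting error of 6.83% to 14.2%. Intervals from reads cover counting error only, since reads without molecular identifiers are not independent molecules. The chi-square per gene between replicates of a group was 1.98 to 7.35 where sampling noise alone gives 1, and all 9 pairs were kept as separate samples.

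Because CPM are not counts, the main test was limma 3.58.1 in R 4.3.3 on log2(CPM + 1) with a mean-variance trend. Fold changes are therefore on the log2(CPM + 1) scale, which understates the change of low genes. Genes with a mean of at least 10 CPM over the libraries compared were tested, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each hairpin was compared with shNTC in its own fit of 6 libraries, and the hairpins were compared with each other in a fit of all 9. Differences are shUsp10-1 minus shUsp10-2. A gene with 0 reads in a group was given a fold bound from a floor of 3 reads over the group, and a gene with 1 to 3 reads a ratio with a 95% counting interval.

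Before the data were examined, 29 gene lists, the tests, most alternative settings and the rule for named genes were fixed. The lists cover WNT target genes, secreted WNT antagonists, WNT pathway components, intestinal stem cell markers, fetal-like and YAP-associated genes, and markers of enterocytes, goblet, Paneth, enteroendocrine and tuft cells. They also cover epithelial identity genes, mesenchymal, immune and endothelial markers, proliferation genes, p53 target genes, MAPK output genes, and NOTCH, BMP and TGF-beta, interferon, NF-kB and stress response genes. The remaining lists hold cholesterol synthesis, hypoxia and glycolysis, NRF2 target, autophagy and lysosome, stress granule and ribosomal protein genes and mitochondrial genome transcripts. Lists with at least 2 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. The rule named, per hairpin, the 10 genes per direction with the largest fold changes among those past the threshold whose hairpin libraries all lay on 1 side of the shNTC libraries. It added the 10 per direction with the largest changes shared by both hairpins, Usp10, Apc, Trp53, Kras and Ctnnb1, and up to 4 members per list. Predicted and unnamed genes were left out, and any other gene named was chosen after its values were seen.

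Genes that share reads with near-identical copies are uncertain, since the handling of such reads is not given in the sources used here. The tables held 39 groups of genes with identical rows (94 genes with at least 50 reads). Positions were taken from GENCODE M21, which uses the same assembly as mm10, and 16716 of the 17399 symbols (96.07%) matched 1 gene; 38 matched more than 1.

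The scripts were tested on simulated reads with 50 genes changed at each fold. The changed genes were drawn from those well above the filter of 10 CPM in shNTC. All genes were given 1 common spread (dispersion 0.00436), so the rates for weaker or more variable genes were not tested. At a fold of 1.25 the test recovered 54% of changed genes for shUsp10-1, 56% for shUsp10-2 and 54% for the difference between the hairpins. At a fold of 1.5 it recovered 98%, 100% and 100%. False calls made up 5.38% of calls for shUsp10-1, 7.29% for shUsp10-2 and 7.33% for the difference, somewhat above the threshold of 5%. A list shifted by 0.5 on the log2 scale was called in both simulated comparisons, together with lists that share its members, and 0 of 24 lists were called without a shift. The simulated genes varied independently of each other, so this does not cover lists whose members vary together. Other splits of the real libraries, which keep part of the difference between the groups, called up to 7 lists. A shift of -0.50 planted on chromosome 13 was measured as -0.49, with every other chromosome within 0.01 of all genes.

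The alternatives were other pseudocounts (0.1 and 5), no filter or a mean of at least 50 CPM, TMM, median-ratio or quantile scaling, no mean-variance trend, a minimum fold change, a replicate block and each library left out. Lists were also tested with an estimated correlation and with fry. Added after the data were seen were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, reads thinned to the shallowest library, the deep shNTC libraries left out and shifted chromosomes left out. On the recovered reads, edgeR called 6504 genes for shUsp10-1 and 6951 for shUsp10-2, and DESeq2 called 6104 and 6545. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Reads, sequence variants and the edits themselves were not analysed here.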

Results

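RNA levels were measured by RNA sequencing in 9 libraries of mouse small intestinal organoids with edits in Apc and Trp53 and the G12D form of Kras. The libraries fell into 3 groups of 3, which carried the hairpin shNTC, shUsp10-1 or shUsp10-2. Usp10 encodes a deubiquitinase, an enzyme that removes ubiquitin from other proteins. The series asks how Usp10 bears on β-catenin and WNT signalling and on stem cell traits in intestinal tumours with a truncated Apc. Libraries held 4972335 to 21450583 recovered reads, and shNTC replicates 1 and 2 were the deepest. The first principal component held 65.9% of the variance of the tested genes and placed the shNTC libraries (-5.80 to -2.58) between shUsp10-1 (47.1 to 52.7) and shUsp10-2 (-47.4 to -44.0). The component after it held 28.5% and set shNTC (35.6 to 36.9) apart from both hairpin groups (-20.7 to -13.8).

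Usp10 itself was lower with both hairpins and lower with shUsp10-2 than with shUsp10-1. The gene lies on chromosome 8 from 119910360 to 119957560 (mm10). Its level was 137 CPM ± 4.60 (SD, n = 3) in shNTC, with 137, 133 and 142 CPM in the 3 libraries. It was 102 CPM ± 8.66 (SD, n = 3) in shUsp10-1, with 94.7, 112 and 100.4 CPM, a change of -25.5% (log2 fold change -0.42, SE 0.0719, limma adjusted p = 0.000171). It was 56.2 CPM ± 3.89 (SD, n = 3) in shUsp10-2, with 54.5, 53.4 and 60.6 CPM, a change of -59.1% (log2 fold change -1.28, SE 0.0671, adjusted p = 5.47e-11). The difference between the hairpins was 0.85 (SE 0.0758, adjusted p = 1.45e-08). An exact two-sided permutation test gave p = 0.1 for each of these comparisons, the smallest value that 3 against 3 samples allow.

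Among the edited genes and β-catenin, Apc did not pass the test with either hairpin (log2 fold changes 0.11 and 0.10, limma adjusted p = 0.412 and 0.283). With shUsp10-2 it passed under median-ratio scaling (adjusted p = 0.0495, range over alternatives 0.0495 to 0.821). Trp53 fell by 0.98 on the log2 scale with shUsp10-1 (adjusted p = 6.17e-07). With shUsp10-2 it fell by 0.20 (adjusted p = 0.00852), and this call was lost under TMM scaling (adjusted p = 0.0782, range over alternatives 0.00463 to 0.191). Kras rose by 0.24 with shUsp10-1 (adjusted p = 0.00541), a call lost without the deep shNTC replicates 1 and 2 (adjusted p = 0.107, range over alternatives 0.000495 to 0.107), and had a log2 fold change of 0.04 with shUsp10-2 (adjusted p = 0.563). Ctnnb1, which encodes β-catenin, rose from 1446 CPM ± 42.8 to 1765 CPM ± 135 (SD, n = 3) with shUsp10-1 (log2 fold change 0.28, adjusted p = 0.00152). Without the deep shNTC replicates that call was lost too (adjusted p = 0.0968, range over alternatives 1.79e-06 to 0.0968). With shUsp10-2 Ctnnb1 was at 1333 CPM ± 36.6 (log2 fold change -0.12, adjusted p = 0.0441), a call lost under TMM scaling (adjusted p = 0.431, range over alternatives 9.11e-05 to 0.625).

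**Figure D1:**
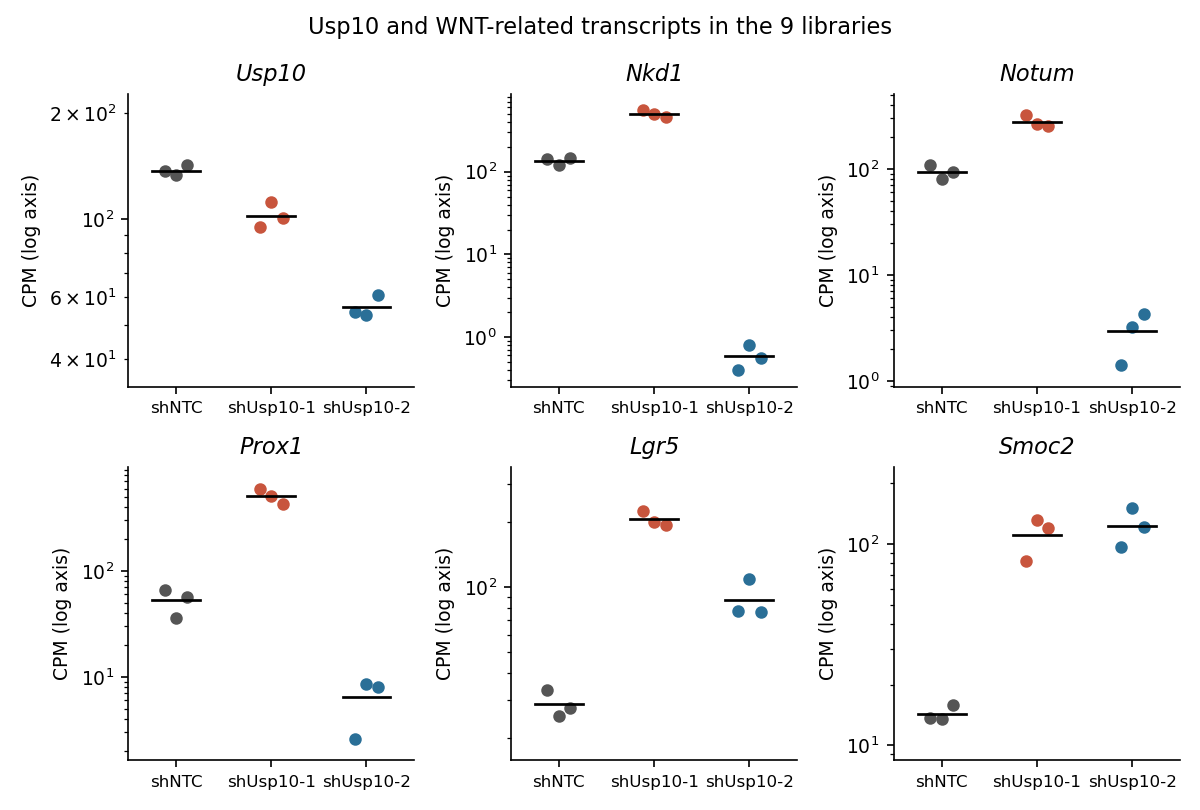
Levels of Usp10 and 5 WNT-related or stem cell transcripts in CPM (log axis) in the 9 libraries; each point is a library, each line a group mean and each column of points a group of 3. Usp10 falls from 137 to 102 and 56.2 CPM, while Nkd1 and Notum lie above shNTC with shUsp10-1 and far below it with shUsp10-2.

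The comparison of shUsp10-1 with shNTC asks what changed with the weaker knockdown. WNT target and stem cell genes were mostly higher, together with cholesterol synthesis and hypoxia genes. Ribosomal protein genes and MAPK output genes were mostly lower. The camera calls of these lists were lost with an estimated correlation (adjusted p = 0.119 to 0.475 with an estimated correlation). Prox1, a homeobox transcription factor, rose from 52.8 CPM ± 15.7 to 514 CPM ± 85.9 (SD, n = 3), a log2 fold change of 3.29 (SE 0.173). Lgr5, the R-spondin receptor that marks intestinal stem cells, rose from 28.8 CPM ± 4.25 to 205 CPM ± 16.4 (SD, n = 3), a log2 fold change of 2.80 (SE 0.0980).

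Of 20 tested WNT target genes, 15 rose, 4 fell and 1 did not pass the test with shUsp10-1, with a median log2 fold change of 0.85. Besides Prox1 and Lgr5 they included Dkk3 (2.78), Tnfrsf19 (2.26), the WNT feedback inhibitor Nkd1 (1.89) and Notum (1.56), which inactivates WNT ligands. Myc (-1.16) and Apcdd1 (-0.67), a membrane inhibitor of WNT, were among those that fell. The list was higher than other genes (limma camera adjusted p = 0.000143), and this call was lost with an estimated correlation (adjusted p = 0.456 with an estimated correlation). The secreted WNT antagonists tested, Notum and Dkk3, both rose (camera adjusted p = 0.0399; adjusted p = 0.456 with an estimated correlation). Dkk3 had a mean of 6.74 CPM in shNTC, so low that a rise was needed for it to be tested. The call of the list was also lost without the mean-variance trend (adjusted p = 0.0652, camera range 0.0114 to 0.0652), and with no filter on low values the median fell from 2.17 to 0.81. Of 20 WNT pathway components, 8 rose, 3 fell and 9 did not pass the test (camera adjusted p = 0.409), with a median of -0.01 and a mean of 0.13. The β-catenin cofactors Bcl9 and Bcl9l rose by 0.99 and 0.89.

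Of 16 tested stem cell markers, 12 rose, 2 fell and 2 did not pass the test (median 0.75, camera adjusted p = 0.000112; adjusted p = 0.119 with an estimated correlation). Smoc2, a secreted matrix-associated protein, rose by 2.85 and Igfbp4 by 1.73. The list shares Lgr5, Axin2 and other members with the WNT target list. All 16 cholesterol synthesis genes rose (median 0.84, camera adjusted p = 1.27e-07; adjusted p = 0.119 with an estimated correlation). They included Dhcr7 (1.46), which makes cholesterol from its last precursor, Insig1 (1.26), Idi1 (1.16) and Hmgcs1 (1.13). Of 16 hypoxia and glycolysis genes, 13 rose, 2 fell and 1 did not pass the test (median 0.73, camera adjusted p = 0.000148; adjusted p = 0.475 with an estimated correlation). Bnip3, a mitophagy receptor induced by hypoxia, rose by 3.09 with a wide spread (118 CPM ± 49.6, SD, n = 3, against 12.6 CPM ± 3.28).

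Of 24 ribosomal protein genes, 22 fell and 2 did not pass the test with shUsp10-1 (median -0.38, camera adjusted p = 0.000107; adjusted p = 0.475 with an estimated correlation). Rps14 fell by 0.80 and Rpl18 by 0.77. Of 18 MAPK output genes, 2 rose, 10 fell and 6 did not pass the test (median -0.46, camera adjusted p = 0.0039; adjusted p = 0.475 with an estimated correlation). The EGF receptor ligands Ereg and Areg fell by 5.18 and 3.62, and the immediate early factors Egr1 and Fosl1 by 2.32 and 2.07. Of 15 p53 target genes, 1 rose, 11 fell and 3 did not pass the test (median -0.33, camera adjusted p = 0.0175; adjusted p = 0.347 with an estimated correlation). Under TMM and median-ratio scaling 8 of them fell, and under quantile normalisation 9. Gdf15, a secreted stress factor, fell by 3.10 and Cdkn1a, which encodes the cell cycle inhibitor p21, by 2.00. The calls of the MAPK and p53 lists were also lost among genes with a mean of at least 50 CPM (adjusted p = 0.0616 and 0.199), with adjusted p from 0.00052 and 0.00424 upwards over the other alternatives. Of 24 proliferation genes, 14 rose, 4 fell and 6 did not pass the test (median 0.22, camera adjusted p = 0.0175; adjusted p = 0.475 with an estimated correlation), with Ccnb2 at 0.91 and Plk1 at 0.81.

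Differentiation markers moved in both directions with shUsp10-1. Of 12 epithelial identity genes, 3 rose and 9 fell (median -0.45, camera adjusted p = 0.0582, from 0.0142 to 0.0831 over the camera alternatives), and the intestinal transcription factors Cdx2 and Hnf4a fell by 2.55 and 1.81. Of 4 goblet cell markers, 1 rose and 3 fell (camera adjusted p = 0.383, but 0.0199 with no filter on low values, range over alternatives 0.0199 to 0.783); Spdef, too low in shNTC to be tested without a rise, rose by 3.65 while Muc2 and Fcgbp fell by 3.27 and 2.68. Of 3 Paneth cell markers, Mmp7 rose by 3.52, Nupr1 fell by 2.33 and 1 did not pass the test (camera adjusted p = 0.799). With no filter on low values the Paneth list turned to a median of -1.80 (adjusted p = 0.0214, range over alternatives 0.0214 to 0.900). All 3 tested enterocyte markers rose (camera adjusted p = 0.0922), among them Apob by 0.59; 1 of the 3 lay just under 10 CPM in shNTC and needed a rise to be tested. That list passed with any shNTC replicate left out and after thinning (range over alternatives 0.0271 to 0.169). Of 2 tuft cell markers, Ptgs1 rose by 2.27 and Avil fell by 1.38 (camera adjusted p = 0.799). Both tested mesenchymal markers rose (camera adjusted p = 0.04; adjusted p = 0.456 with an estimated correlation). The list's call was also lost with no filter on low values, where its median was 0.0342 in place of 1.70 (adjusted p = 0.0927), under quantile normalisation (adjusted p = 0.0649) and without the mean-variance trend (adjusted p = 0.0652), with a camera range from 0.0197 to 0.0927. Fn1, fibronectin, rose from 719 CPM ± 29.2 to 4400 CPM ± 176 (SD, n = 3). Vim rose by 0.80 (adjusted p = 0.0021), and by 0.53 without shNTC replicate 2 (adjusted p = 0.0047, range over alternatives 3.27e-05 to 0.102). Without shNTC replicates 1 and 2 it stood at 0.38 and the call of Vim was lost (adjusted p = 0.102). The immune marker Cd68 rose by 1.12 and the endothelial marker Tek by 2.46, each the only member of its list that was tested and under 10 CPM in shNTC, so that only a rise could bring it into the test. No enteroendocrine marker passed the filter on low values, with 8 of the list in the tables.

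In the remaining lists, 8 of 13 NRF2 target genes fell and 1 rose (camera adjusted p = 0.0595, but 0.00794 with no filter on low values, range over alternatives 0.00794 to 0.735), with the glutathione transferase Gsta1 at -3.72. Of 18 stress response genes, 7 rose and 10 fell (camera adjusted p = 0.184), and the integrated stress response factors Ddit3, Ppp1r15a and Trib3 fell by 2.60, 2.04 and 1.94. Of 18 fetal-like and YAP-associated genes, 8 rose and 8 fell; the list's median was -0.11 and its mean -0.12, while camera ranked it higher (adjusted p = 0.799). Spp1, osteopontin, rose by 3.13. Of 15 autophagy and lysosome genes, 4 rose and 4 fell (adjusted p = 0.799), and the autophagy receptor Sqstm1 fell by 1.96. Of 11 stress granule genes, 5 rose and 0 fell (adjusted p = 0.119), with G3bp1, whose protein binds USP10, at 0.26. Of 8 NOTCH pathway genes, 3 rose and 2 fell (adjusted p = 0.766). Of 9 BMP and TGF-beta response genes, 4 rose and 3 fell (adjusted p = 0.696). Of 6 interferon response genes, 2 rose and 2 fell (adjusted p = 0.805), and of 8 NF-kB target genes 2 rose and 2 fell (adjusted p = 0.673). Adjusted over the list alone, the counts of each list with shUsp10-1 were those over all genes tested, except that 23 ribosomal protein genes fell.

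The largest single increases with shUsp10-1 were those of the gastric peptide gene Gkn3 (6.09, from 1.81 to 191 CPM), lactoferrin Ltf (4.91), N-cadherin Cdh2 (4.81), the WNT ligand Wnt6 (4.78) and the water channel Aqp5 (4.32). Antxr1, Hs6st2, Ifitm1 and Cpxm2 rose by 4.30, 4.23, 4.20 and 4.14. The WNT ligand Wnt10a rose by 3.99. The largest decreases were those of the glycosyltransferase B4galnt2 (-5.76), the brush border cadherin Cdhr5 (-5.47), Rps4l (-5.45), the RNA-binding protein gene Qk (-5.35), Il5ra and the desmosomal cadherin Dsg3 (-5.20 each). Wfdc2 fell by 5.19, Ereg by 5.18 and Myo15b by 5.01. Qk had 2064 reads in shNTC and 1 in shUsp10-1, a ratio of 826 (95% counting interval 148 to 32641). Muc3, a membrane mucin of the intestine, had 1210 reads in shNTC and 0 in shUsp10-1 and was at least 161-fold lower.

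Of 10272 genes tested for shUsp10-1, 6524 changed by limma, 2919 upwards and 3605 downwards. The balance of directions depended on the method, with 3083 upwards and 3367 downwards under median-ratio scaling, 3246 and 3258 by edgeR and 3088 and 3016 by DESeq2. The change was at least 1 on the log2 scale in 627 higher and 424 lower genes. The groups did not overlap in 68.0% of genes, where chance gives 10%. With the deep shNTC replicates 1 and 2 left out, 4152 genes passed the test, with the lone shNTC library assumed to vary like the other groups. Among genes with a mean of at least 50 CPM, 3600 of 5353 passed.

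**Figure D2:**
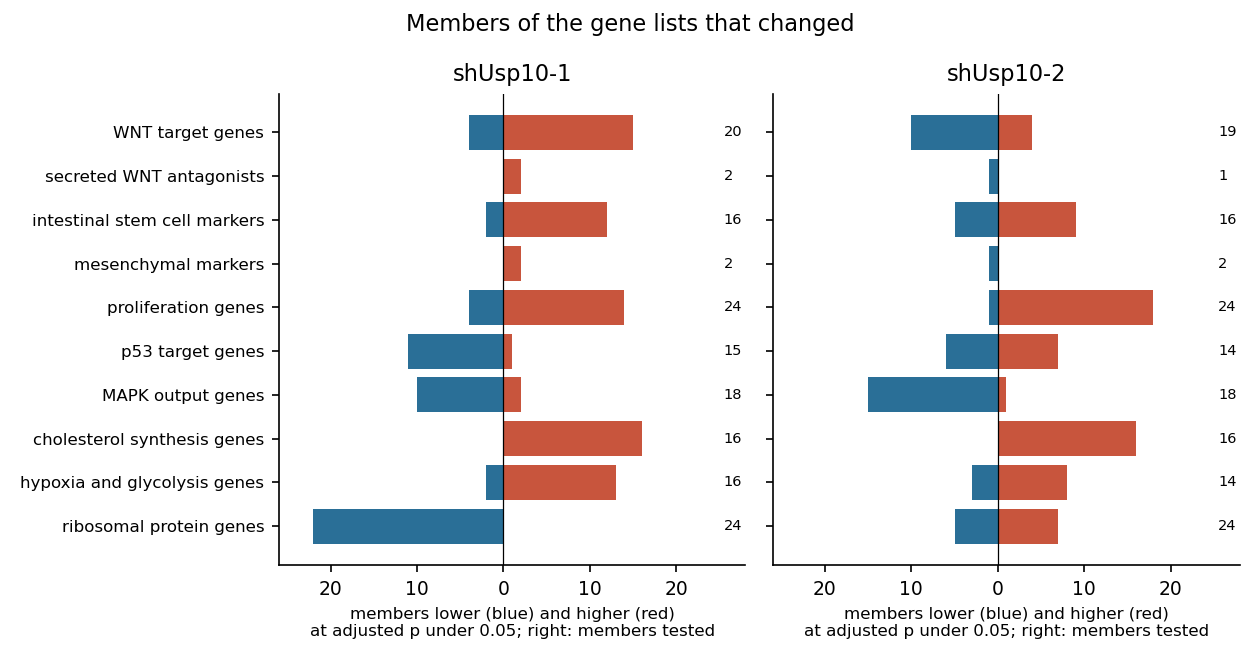
Number of members of the 10 gene lists past the test with either hairpin that were lower (blue bars, to the left) or higher (red bars, to the right) at adjusted p under 0.05, for shUsp10-1 and shUsp10-2; the number at the right of each panel is that of members tested. With an estimated correlation 0 lists passed for shUsp10-1 and 0 for shUsp10-2. All 16 cholesterol synthesis genes are higher with both hairpins. Of the WNT target genes, 15 of 20 are higher with shUsp10-1 and 10 of 19 lower with shUsp10-2.

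The comparison of shUsp10-2 with shNTC asks what changed with the stronger knockdown. The WNT inhibitor genes Nkd1 and Notum were far lower, while Lgr5 and Smoc2 were higher. All 16 cholesterol synthesis genes and 18 of 24 proliferation genes rose, and 15 of 18 MAPK output genes fell. The camera calls of these lists were lost with an estimated correlation (adjusted p = 0.113, 0.21 and 0.113 with an estimated correlation). Nkd1 fell from 136 CPM ± 13.7 to 0.587 CPM ± 0.201 (SD, n = 3), a log2 fold change of -6.43 (SE 0.137). Notum fell from 94.5 CPM ± 13.9 to 2.97 CPM ± 1.45 (SD, n = 3), a log2 fold change of -4.65 (SE 0.207).

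Of 19 tested WNT target genes, 4 rose, 10 fell and 5 did not pass the test with shUsp10-2 (median -0.21, camera adjusted p = 0.241). Besides Nkd1 and Notum, Prox1 (-2.94) and Apcdd1 (-2.79) fell. Lgr5 rose to 87.3 CPM ± 18.3 (log2 fold change 1.56, SE 0.123), Ascl2 by 1.26, and Axin2 and Tnfrsf19 by 0.30 and 0.29. Notum was the only secreted WNT antagonist tested. Dkk3, below the filter, had 318 reads in shNTC and 3 in shUsp10-2, a ratio of 38.7 (95% counting interval 13.1 to 189). Of 20 WNT pathway components, 3 rose, 12 fell and 5 did not pass the test (camera adjusted p = 0.387), while 8 fell under TMM scaling. They included Dvl3 at -0.81, the tankyrase gene Tnks at -0.79 and Gsk3b at -0.77. Of 16 stem cell markers, 9 rose, 5 fell and 2 did not pass the test (camera adjusted p = 0.214). Smoc2 rose by 3.0 and Slc12a2 by 1.27, while the RNA-binding protein gene Mex3a fell by 2.41.

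All 16 cholesterol synthesis genes rose with shUsp10-2 (median 1.07, camera adjusted p = 7.31e-10; adjusted p = 0.113 with an estimated correlation). Idi1, Dhcr24, Cyp51 and Insig1 rose by 2.07, 1.69, 1.63 and 1.61. Of 24 proliferation genes, 18 rose, 1 fell and 5 did not pass the test (median 0.43, camera adjusted p = 1.44e-05; adjusted p = 0.21 with an estimated correlation). The mitotic genes Cdc20, Ccna2 and Plk1 rose by 1.16, 1.01 and 0.93. Of 18 MAPK output genes, 1 rose, 15 fell and 2 did not pass the test (median -0.69, camera adjusted p = 6.78e-05; adjusted p = 0.113 with an estimated correlation). The ETS factor Etv5 fell by 2.35, Egr1 by 2.31, Areg by 2.13 and Ereg by 1.33.

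The other lists did not pass camera with shUsp10-2, apart from the Paneth list with no filter on low values. Of 14 p53 target genes, 7 rose and 6 fell (adjusted p = 0.664); Gdf15 fell by 3.16, Sesn2 by 2.29 and Cdkn1a by 1.65. The median of that list was 0.05, while its mean was -0.57 and camera ranked it lower. Of 18 stress response genes, 5 rose and 12 fell (adjusted p = 0.179), with Trib3 at -3.29, Chac1, which degrades glutathione, at -2.48 and Ddit3 at -2.23. Of 14 hypoxia and glycolysis genes, 8 rose and 3 fell (adjusted p = 0.664), with Vegfa at -2.54 and the glucose transporter gene Slc2a1 at -1.77; the median was 0.22 and the mean -0.21. Of 24 ribosomal protein genes, 7 rose, 5 fell and 12 did not pass the test (adjusted p = 0.387), and adjusted over the list alone 6 rose; the counts of the other lists were the same adjusted over the list alone. Under TMM scaling 11 ribosomal protein genes rose and 2 fell, and under median-ratio scaling 13 rose and 2 fell. Rpl8 rose by 0.64 and Rps2 by 0.60, while Rpl7 fell by 0.41. Of 14 NRF2 target genes, 3 rose and 7 fell (adjusted p = 0.664), with the cystine transporter gene Slc7a11 at -1.80 and Gpx2 at 1.24.

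Of 12 epithelial identity genes, 5 rose and 4 fell with shUsp10-2 (adjusted p = 0.669), and the transcription factor Gata6 fell by 3.47; the median was 0.01 and the mean -0.23, while camera ranked the list higher. Under TMM and median-ratio scaling 2 of that list fell, and under quantile normalisation 3 rose and 5 fell. Cdx2 had a log2 fold change of -0.01 (adjusted p = 0.901). Of 4 goblet cell markers, 2 rose and 1 fell (adjusted p = 0.664), with a median of 0.43 and a mean of -0.22. Muc2 stood at -2.94 and the secreted trefoil peptide Tff3 at 1.20. Tff3 lay below the filter in shNTC (291 reads), so a rise was needed for it to be tested. Of 2 Paneth cell markers, Mmp7 rose by 1.03 and Nupr1 fell by 2.55 (median -0.76, adjusted p = 0.772). With no filter on low values that list passed camera, with a median of -2.25 (adjusted p = 0.00823, range over alternatives 0.00823 to 0.877). Of 2 enterocyte markers, Apob rose by 1.62 and 1 did not pass the test (adjusted p = 0.484). Of 2 tuft cell markers, Ptgs1 rose by 0.79 and Avil fell by 2.44 (adjusted p = 0.867). Of 2 mesenchymal markers, Fn1 fell by 1.56 and Vim did not pass the test (-0.31; adjusted p = 0.392 for the list). Without shNTC replicate 2, Vim passed it at -0.58 (adjusted p = 0.00717, range over alternatives 0.00717 to 0.681). No immune, endothelial or enteroendocrine marker passed the filter on low values.

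Of 18 fetal-like and YAP-associated genes, 8 rose and 8 fell (adjusted p = 0.664; median -0.15, mean 0.02), with the YAP target Ccn1 at 1.99. Of 15 autophagy and lysosome genes, 4 rose and 7 fell (adjusted p = 0.664; median 0.02, mean -0.22), with Sqstm1 at -1.74. Under median-ratio scaling 7 of them rose. Of 11 stress granule genes, 7 rose and 1 fell (adjusted p = 0.214), with G3bp1 at 0.45. Of 7 NOTCH pathway genes, 3 rose and 3 fell (adjusted p = 0.702; median -0.05, mean 0.15), with Lfng at 1.51. Of 8 BMP and TGF-beta response genes, 5 rose and 2 fell (adjusted p = 0.387), with the BMP target Id2 at 1.96. Of 6 interferon response genes, 1 rose and 4 fell (adjusted p = 0.387), with Stat1 at -0.76. Of 9 NF-kB target genes, 2 rose and 3 fell (adjusted p = 0.668), with Tnfaip2 at -2.39.

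The largest single increases with shUsp10-2 were those of the water channel Aqp1 (4.56, from 5.35 to 150 CPM), Zscan4c (3.98), Pramel39 (3.84), Zscan4f (3.72), Dsg1c (3.39), Rab15 (3.12), Ugt2b35 (3.04) and Smoc2 (3.0). Pramel37 and Pramel50 had identical rows (3.72), and the Zscan4 and Pramel genes may share reads with near-identical copies. The largest decreases after Nkd1 were those of the adaptor Grb10 (-6.19), the amino acid transporter Slc7a3 (-5.80), Wfdc2 (-5.41), Ifitm3 (-5.11), Qk (-5.08) and Prkaa2 (-5.00), which encodes a catalytic subunit of AMPK. Tbc1d9 and Bex1 fell by 4.52 each. Grb10 had 4021 reads in shNTC and 3 in shUsp10-2, a ratio of 490 (95% counting interval 167 to 2376), and Prkaa2 had 1696 and 2, a ratio of 310 (85.7 to 2561).

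Of 10023 genes tested for shUsp10-2, 6941 changed by limma, 2980 upwards and 3961 downwards. The balance of directions depended on the scaling, with 3442 upwards and 3436 downwards under TMM and 3569 and 3318 under median-ratio scaling. The change was at least 1 on the log2 scale in 370 higher and 519 lower genes. The groups did not overlap in 72.2% of genes, where chance gives 10%. Among genes with a mean of at least 50 CPM, 3994 of 5291 passed.

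The medians of several chromosomes lay off that of all genes with shUsp10-2, and the 5 farthest off were 13, 18, 19, 1 and 16. The median log2 fold change relative to all genes was -0.54 on chromosome 13, where 14.0% of 342 genes lay above the median of all genes. It was 0.50 on chromosome 18, which holds Apc, 0.36 on chromosome 19, -0.28 on chromosome 1 and -0.22 on chromosome 16. Chromosomes 6 (0.18), 15 (0.17), X (0.11) and 4 (-0.10) followed. The set of 5 was chosen after these values were seen. The shUsp10-2 libraries ranged from -0.57 to -0.52 on chromosome 13 and from 0.48 to 0.51 on chromosome 18. With shUsp10-1 each library lay within 0.0902 of all genes on every autosome and within 0.143 on chromosome X. With those 5 chromosomes left out, 5341 of 7959 genes still passed the test with shUsp10-2 and 3 lists passed camera, though 0 did with an estimated correlation over all chromosomes (adjusted p = 0.113, 0.21 and 0.113 for the cholesterol, proliferation and MAPK lists). Of the genes named up to here for shUsp10-2, Idi1 lies on chromosome 13 and Apcdd1, Slc12a2, Gata6, Egr1 and Dsg1c on chromosome 18. Prox1, Fn1, Stat1 and Rpl7 lie on chromosome 1, and Dvl3, Gsk3b and Etv5 on chromosome 16. Genes named only further on are not placed here and may also lie on these chromosomes.

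**Figure D3:**
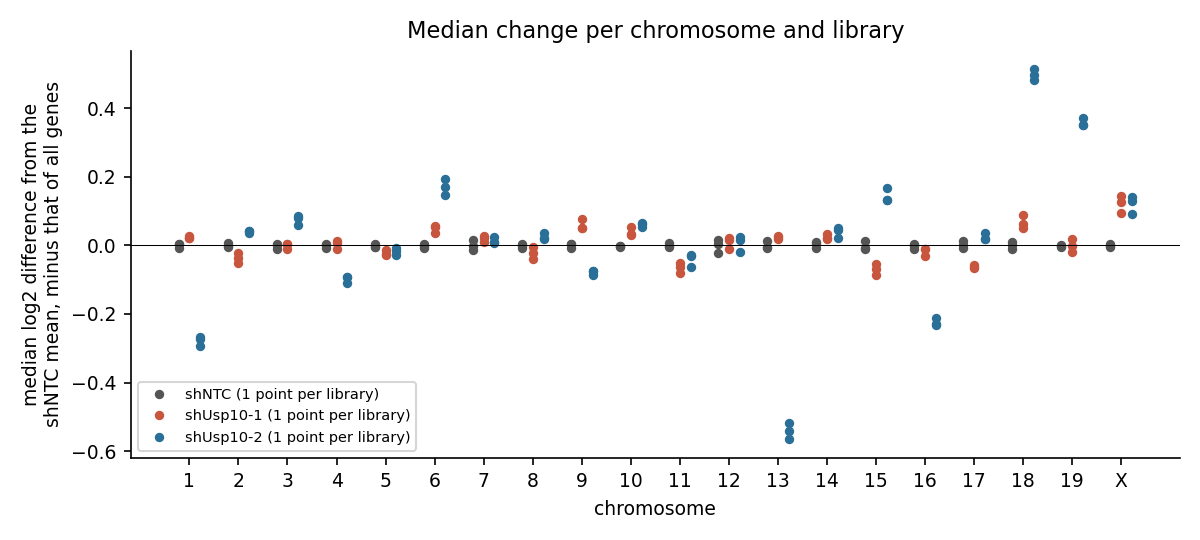
Median log2 difference from the shNTC mean over the genes of each chromosome, minus that of all genes, with 1 point per library of shNTC, shUsp10-1 and shUsp10-2; the horizontal axis gives the chromosome. The shUsp10-2 libraries lie between -0.57 and -0.52 on chromosome 13 and between 0.48 and 0.51 on chromosome 18. The shNTC libraries lie within 0.0214 of 0 throughout, in part because the values are differences from their own mean.

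Genes that moved the same way with both hairpins address what the knockdowns had in common. The desaturase gene Fads2 rose by 2.90 with shUsp10-1 and 2.55 with shUsp10-2, Smoc2 by 2.85 and 3.0, and Aldh1a7 by 2.95 and 2.31. Nexmif rose by 2.75 and 2.26, Fgfbp1 by 2.27 and 2.52, the semaphorin and VEGF coreceptor gene Nrp1 by 3.21 and 2.04 and Kif12 by 3.46 and 2.02. Tgm2, a transglutaminase, rose by 1.95 and 1.89. The histone genes H2ac23 and H2ac24, with identical rows, rose by 2.08 and 2.13. In the other direction went Wfdc2 (-5.19 and -5.41), Qk (-5.35 and -5.08) and Ly6g (-3.79 and -3.77). The sterol acyltransferase gene Soat2 (-3.18 and -3.20), Gdf15 (-3.10 and -3.16), Bcl2l15 (-3.37 and -3.01), the goblet mucin gene Muc2 (-3.27 and -2.94) and Ugt1a7c (-2.92 and -3.04) also fell with both.

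Of 9818 genes tested with both hairpins, 4425 changed with both, and 3094 of these (69.9%) went the same way, 1142 upwards and 1952 downwards. The downward excess depended on the method, with 1358 upwards and 1573 downwards under median-ratio scaling, 1380 and 1601 by edgeR and 1297 and 1406 by DESeq2. Without the deep shNTC replicates 1 and 2, 1816 genes went the same way, with the lone shNTC library assumed to vary like the other groups. Independent lists of these sizes would share 747.6 and 1438 genes. The shares higher and lower among the 4425 genes would by chance put 2286 the same way, and the real number was 1.35 times that. With a different single shNTC library as the control of each hairpin, 1606 to 1724 genes went the same way, 1.36 to 1.48 times the number by chance over the 6 pairs of libraries. In these fits the lone shNTC library was assumed to vary like the hairpin group, and the controls still came from 1 shNTC group. The correlation of the log2 fold changes across genes, which are not independent replicates, was 0.283. Shared shNTC libraries alone give a correlation, with a mean of 0.50 over 100 simulations of unchanged groups. Those simulations hold noise only, so the 0.50 does not carry over to groups with many changed genes. The covariance, which keeps the size of the changes, was at most 0.00572 in them and 0.120 in the data. With shUsp10-1 or shUsp10-2 as the reference the covariance was 0.478 and 0.327 and the correlation 0.722 and 0.625. Neither 0.120 nor 0.283 therefore measures agreement between the hairpins.

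**Figure D4:**
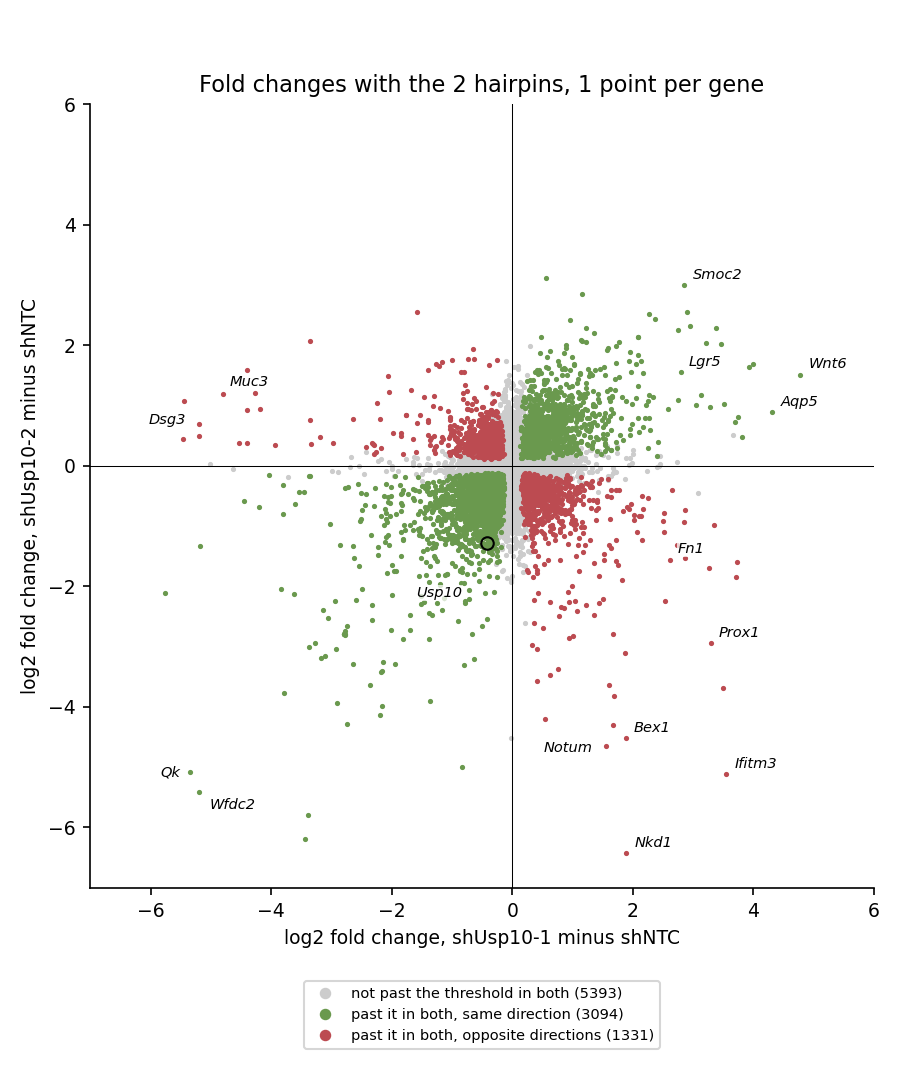
Log2 fold change of each gene tested with both hairpins, shUsp10-1 minus shNTC on the horizontal axis and shUsp10-2 minus shNTC on the vertical axis; each point is a gene, and Usp10 is ringed. Of the genes past the test with both, 3094 (green) lie in the quadrants of equal direction and 1331 (red) in those of opposite direction, among them Nkd1, Ifitm3 and Notum.

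The direct comparison of the hairpins asks whether they acted alike. WNT target genes were mostly higher with shUsp10-1 than with shUsp10-2, and ribosomal protein genes mostly lower (adjusted p = 0.35 and 0.455 with an estimated correlation). Nkd1 was at 506 CPM ± 44.4 with shUsp10-1 against 0.587 CPM ± 0.201 with shUsp10-2 (SD, n = 3; log2 difference 8.32, SE 0.106). Ifitm3 was at 493 CPM ± 24.6 against 0.218 CPM ± 0.0428 (difference 8.66, SE 0.106). The desmosomal gene Dsg3 was at 8.57 CPM ± 0.979 against 569 CPM ± 41.0 (difference -5.90, SE 0.0774).

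Of 20 WNT target genes, 17 were higher and 2 lower with shUsp10-1 than with shUsp10-2 (median 1.01, camera adjusted p = 1.15e-05; adjusted p = 0.35 with an estimated correlation). Prox1 differed by 6.23, Notum by 6.21, Dkk3 by 5.45 and Lgr5 by 1.24. Both secreted antagonists were higher with shUsp10-1 (median 5.83, or 7.26 with Dkk3 at its read ratio; camera adjusted p = 0.0373; adjusted p = 0.35 with an estimated correlation). With no filter on low values the median was 0.98, and without the mean-variance trend the call was lost (adjusted p = 0.0658, camera range 0.0137 to 0.0658). Dkk3 had 1037 reads with shUsp10-1 and 3 with shUsp10-2, a ratio of 316 (95% counting interval 108 to 1533), and passed the filter only through its level with shUsp10-1. Of 15 hypoxia and glycolysis genes, 12 were higher and 0 lower (median 0.69, camera adjusted p = 0.0111; adjusted p = 0.609 with an estimated correlation), with Bnip3 at 3.54 and Slc2a1 at 2.18. Of 24 ribosomal protein genes, 0 were higher and 22 lower (median -0.51, camera adjusted p = 1.15e-05; adjusted p = 0.455 with an estimated correlation), with Rps14 at -1.02 and Rpl8 at -0.96. Adjusted over the list alone, the counts of these 4 lists were the same.

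The remaining lists did not pass camera in this comparison, and the tuft, mesenchymal and NRF2 lists passed under some alternatives (lowest adjusted p = 0.0406, 0.0438 and 0.0452, highest 0.289, 0.289 and 0.448). The cholesterol synthesis list had 2 members higher and 8 lower with shUsp10-1 (adjusted p = 0.0634), the stem cell list 10 higher and 3 lower (adjusted p = 0.0645), and the WNT pathway components 14 higher and 2 lower (adjusted p = 0.0523). Each of these lists passed under some alternatives, with adjusted p from 0.0133 to 0.146 for cholesterol synthesis, from 0.0133 to 0.112 for stem cell markers and from 0.0121 to 0.0658 for WNT pathway components. For the epithelial identity list the counts were 3 higher and 8 lower (adjusted p = 0.0634, range over alternatives 0.0154 to 0.176), for proliferation genes 4 and 11 (adjusted p = 0.108) and for MAPK output genes 6 and 8 (adjusted p = 0.642). Adjusted over the list alone, 3 WNT pathway components were lower and the counts of the other lists were the same. The autophagy and lysosome list had 4 members higher and 5 lower (median -0.13, mean 0.10, adjusted p = 0.976), and the stress granule list 4 higher and 4 lower (median -0.09, mean 0.05, adjusted p = 0.953), with camera ranking the former higher and the latter lower. In this comparison 7156 of 10185 genes passed limma's test, 3675 higher and 3481 lower with shUsp10-1. Which direction held more genes depended on the method, with 3484 higher and 3674 lower under TMM scaling, 3413 and 3785 under median-ratio scaling, 3299 and 3863 under quantile normalisation and 3424 and 3484 by DESeq2. All 1331 genes that went opposite ways with the hairpins were among them (712 higher with shUsp10-1 and lower with shUsp10-2, and 619 the reverse). Independent lists would hold 2074 such genes.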

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

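The chromosome pattern below was chosen after the data had been seen, and so were the tests on scaling, on depth of knockdown, on chance through the shNTC libraries, on lines that drifted apart, on loss of chromosome 13 and on gain of chromosome 18. Thinning of the reads was also added after the data were seen. For the number of changed genes, the expectations on depth and on the nearest genes were taken out after both tests had been run. The other tests were set before their results were seen. The results in this part stand out because the 2 hairpins, both directed at Usp10, differed from each other by limma's test of the difference itself. In all, 7156 genes differed, and 1331 of the genes changed by both hairpins went opposite ways. Of the lists, WNT target genes (median log2 difference 1.01), secreted WNT antagonists (5.83), hypoxia and glycolysis genes (0.69) and ribosomal protein genes (-0.51) differed by camera. All 4 calls were lost with an estimated correlation (adjusted p = 0.35, 0.35, 0.609 and 0.455 with an estimated correlation). Of the genes named in the text, 115 differed, 64 of them higher and 51 lower with shUsp10-1.

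Log2 differences of at least 4 towards shUsp10-1 were those of Ifitm3 8.66, Nkd1 8.32, Gkn3 6.62, Ltf 6.42, Bex1 6.40, Prox1 6.23, Notum 6.21, Hs6st2 6.02, Cpxm2 5.83, Cdh2 5.62, Dkk3 5.45, Muc6 5.33, Ifitm1 5.30, Tbc1d9 4.50, Tek 4.32, Prkaa2 4.17, Fn1 4.17, Gata6 4.09 and Antxr1 4.0. From 2 to 4 lay Gkn1 3.94, Spdef 3.93, Bnip3 3.54, Mex3a 3.48, Aqp5 3.43, Wnt6 3.27, Etv5 3.21, Grb10 2.75, Mmp7 2.49, Slc7a3 2.41, Wnt10a 2.31, Slc2a1 2.18, Igfbp4 2.12, Vegfa 2.12 and Apcdd1 2.12. From 1 to 2 lay Tnfrsf19 1.97, Spp1 1.96, Ptgs1 1.49, Kif12 1.44, Cd68 1.36, Trib3 1.34, Lgr5 1.24, Tnfaip2 1.22, Bcl9 1.20, Nrp1 1.18, Vim 1.10, Avil 1.06 and Axin2 1.03. Under 1 lay Ctse 0.95, Hmgcs1 0.92, Usp10 0.85, Chac1 0.78, Sesn2 0.78, Dvl3 0.76, Slc7a11 0.73, Aldh1a7 0.63, Gsk3b 0.58, Bcl9l 0.57, Nexmif 0.49, Ccnb2 0.44, Ctnnb1 0.40, Tnks 0.37, Fads2 0.35, Nupr1 0.22 and Kras 0.20. Towards shUsp10-2, differences of at least 3 were those of Lgals4 -3.19, Myo1a -3.35, Gsta1 -3.53, B4galnt2 -3.65, Pramel39 -3.67, Zscan4c -3.83, Ereg -3.84, Cdhr2 -3.88, Cdh17 -3.88, Ugt2b35 -4.0, Aqp1 -4.47, Myo15b -5.04, Il5ra -5.69, Dsg3 -5.90, Cdhr5 -5.92, Muc3 -5.99 and Rps4l -6.53. Between these and -1 lay Rps14 -1.02, Apob -1.03, Gpx2 -1.14, Fosl1 -1.15, Slc12a2 -1.39, Areg -1.49, Anxa10 -1.65, Hnf4a -2.00, Cdx2 -2.54, Rab15 -2.57, Fcgbp -2.82, Dsg1c -2.93 and Tff1 -2.95. Smaller ones were those of G3bp1 -0.19, Sqstm1 -0.22, Fgfbp1 -0.26, Ccn1 -0.26, Vsig1 -0.29, Insig1 -0.36, Ddit3 -0.37, Id2 -0.38, Cdc20 -0.45, Ascl2 -0.56, Rpl18 -0.56, Ccna2 -0.62, Dhcr24 -0.66, Krt18 -0.71, Rps2 -0.72, Ppp1r15a -0.73, Myc -0.77, Cyp51 -0.77, Trp53 -0.78, Idi1 -0.91 and Rpl8 -0.96. Values of genes with few reads in a group are held down by the log2(CPM + 1) scale. Muc3 had 0 reads with shUsp10-1 and was at least 414-fold lower than with shUsp10-2. Read ratios of shUsp10-1 to shUsp10-2 were 40.5 for Grb10 (95% counting interval 13.6 to 199), 174 for Prkaa2 (47.8 to 1442) and 316 for Dkk3 (108 to 1533). Under quantile normalisation the differences of Grb10 and Slc7a3 were 1.75 and 1.31. The calls of Kras, Fgfbp1, Ccn1, Ddit3 and Nupr1 were lost under some alternatives (highest adjusted p = 0.0770, 0.136, 0.0609, 0.107 and 0.0715; lowest 0.00824, 0.00703, 0.00231, 0.00143 and 0.00659).

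The WNT target genes moved apart although both hairpins lowered Usp10. Scaling between libraries does not account for it, since the lowest median difference over 3 scalings was 0.96. Copy number of broad chromosome stretches does not account for it either, with a median of 1.04 after the 50 nearest genes were subtracted. Copy number of single genes would not show in this subtraction and was not tested. A different depth of Usp10 knockdown alone would move each gene the same way only if its response kept 1 direction, which was not tested. Of the 13 list members changed with both hairpins, 5 went opposite ways (38.5%) and 8 the same way. Over all 4425 genes changed with both, 69.9% went the same way. Depth alone, with 1 direction per gene, does not account for those 5 members. A response that turns with depth, effects of a hairpin on other transcripts and traits of the cultures that existed before were not tested. Any of these may be the cause.

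Sampling noise of shared shNTC libraries does not account for the genes that changed the same way with both hairpins, since with a different shNTC library as the control of each hairpin they were still at least 1.36 times as many as chance would give. A graded response to the depth of Usp10 knockdown cannot be told apart from its absence, with 52.6% of the graded genes changed more with shUsp10-2. Lines that drifted apart, with nothing shared by the hairpins, could give such a count, since a hairpin group as the reference gave up to 4158 genes against 3094 with shNTC. The design holds 1 control hairpin, so a trait peculiar to the shNTC samples could also account for part of the 3094, and this was not tested.

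With shUsp10-2 the medians of several chromosomes lay off that of all genes, those of 13, 18, 19, 1 and 16 the farthest, followed by 6 (0.18) and 15 (0.17). GC content and length of the genes do not account for the shifts of chromosomes 13 and 18, with chromosome 13 at -0.56 and chromosome 18 at 0.49 after a fit on both. Weakly expressed genes do not account for the shift of chromosome 13, which was -0.56 at a mean of at least 50 CPM and a pseudocount of 0.1. Loss of chromosome 13 in the shUsp10-2 samples may be the cause of its shift, since of 4 segments with similar numbers of genes the segment nearest to all genes lay at -0.51, but DNA was not measured and the test was set after the shift was seen. By the same test, gain of chromosome 18 cannot be told apart from a shift of part of it, because its segment nearest to all genes lay at 0.27. In that segment 23 of the 69 genes are protocadherin genes with shared reads. Without them it lay at 0.53, beside 0.51, 0.52 and 0.59 in the other segments. These values argue against a shift of only some of the segments, but DNA was not measured and the test was set after the shift was seen.

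Depth and chromosomes do not account for the number of changed genes. With all libraries thinned to the depth of the shallowest, 6103 in place of 6524 genes changed with shUsp10-1 and 6680 in place of 6941 with shUsp10-2. With the 50 nearest genes subtracted, 6229 in place of 6377 changed with shUsp10-1 and 6498 in place of 6790 with shUsp10-2.

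Regrouping the 6 libraries of a comparison allows 10 splits, too few for a share under 0.05. For shUsp10-1, 1 split reached the real 6524 genes (highest other 0) and 1 the real 10 lists (highest other 7). For shUsp10-2, 1 split reached the real 6941 genes (highest other 0) and 9 the real 3 lists (highest other 7). The number of lists with shUsp10-2 was thus no higher than in most other splits. Those splits mix the groups unevenly and keep part of the real difference, so they cannot show what chance alone gives. For the difference, 1 split reached the real 7156 genes (highest other 0). Of 100 splits drawn from the 9 libraries, 2 reached the real 3094 genes changed the same way. The highest other, 3784, kept the groups whole with another reference, and the highest that mixed groups gave 2222.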

How the results depend on the processing

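The level of Usp10 kept its direction and its call under each alternative in which it was tested, which leaves out the minimum fold change, and lay from -0.49 to -0.37 with shUsp10-1 and from -1.33 to -1.24 with shUsp10-2 over each library left out in turn. Over the same, 5685 to 6676 genes changed with shUsp10-1, 6240 to 6875 with shUsp10-2, 6798 to 7072 between the hairpins and 2521 to 3309 the same way with both, while 10 to 13 and 3 to 3 lists passed. Among genes with a mean of at least 50 CPM these counts were 3600, 3994, 3946 and 1851, with fewer genes tested. With an absolute log2 fold change of at least 1 they were 1051, 889, 1438 and 212, by the stricter rule. With an estimated correlation 0 lists passed for shUsp10-1 and 0 for shUsp10-2, and with fry 21 and 19; the cause was not tested. Without the deep shNTC replicates 1 and 2, 4152 genes changed with shUsp10-1 and 1816 the same way with both, with fewer samples and the lone shNTC library assumed to vary like the other groups. The Paneth list with shUsp10-1 turned to -1.80 with no filter on low values (adjusted p = 0.0214, range over alternatives 0.0214 to 0.900), where more of its members were tested. Krt18 with shUsp10-2 turned to -0.0366 under quantile normalisation (adjusted p = 0.515, range 2.55e-15 to 0.515); the cause was not tested. Over the named genes, 7245 comparisons with an alternative were the same, 94 weaker, 21 stronger and 1 reversed, and with a library left out 3466 were the same, 62 weaker and 11 stronger. Over the lists, 834 were the same, 7 weaker, 29 stronger and 1 reversed, and with a library left out 508 were the same and 11 stronger.

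Around their group means, libraries with the same replicate number correlated at -0.232 to 0.110 and those with other numbers at -0.337 to 0.329. The same number thus went with no closer match than another number. With 3 libraries per group this cannot show whether the samples were paired. With the number as a block, 6427 genes changed with shUsp10-1, 6934 with shUsp10-2, 7094 between the hairpins and 3035 the same way with both. The call of Ctnnb1 with shUsp10-2 was lost under the block (adjusted p = 0.0521), and the epithelial identity list with shUsp10-1 gained its call (camera adjusted p = 0.0462). Without the block, camera gave that list an adjusted p of 0.456 with an estimated correlation. Lists were not tested with edgeR or DESeq2. DESeq2 was set for counts only, and as the values were CPM it was run on recovered reads as an addition.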

Other observations

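The groups of genes in this part were chosen after their values had been seen, so no p-value of a list is given. Gastric epithelium genes outside the lists fixed beforehand moved with shUsp10-1, where 6 of 8 tested rose and 2 fell by limma, though Gkn1 and Gkn3 lay so low in shNTC that a rise was needed to be tested. The gastrokine gene Gkn1 rose from 3.72 CPM ± 0.340 to 28.3 CPM ± 3.65 (SD, n = 3), and the gland mucin gene Muc6 from 16.3 CPM ± 9.34 to 203 CPM ± 64.4. Vsig1 rose by 1.77 on the log2 scale and the aspartic protease gene Ctse by 0.95, beside Gkn3 and Aqp5. Tff1 (-1.26) and Anxa10 (-2.01) fell. With shUsp10-2, 3 of 6 tested rose and 2 fell: Vsig1 rose by 2.06, more than with shUsp10-1, Tff1 by 1.68 and Aqp5 by 0.88, while Muc6 stood at -1.60. Brush border and adhesion genes of the intestine were lower with shUsp10-1 in 8 of 9 tested. The cadherin gene Cdh17 fell from 1333 CPM ± 59.4 to 81.1 CPM ± 11.7 (SD, n = 3), and the galectin gene Lgals4 from 1892 CPM ± 90.4 to 186 CPM ± 32.4. Cdhr2 (-4.46) and Myo1a (-2.98) fell as well. With shUsp10-2, 5 of 9 rose and 4 fell, and Cdh17 stood at 1202 CPM ± 47.8.

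Some genes known from the 2-cell stage of the mouse embryo were higher with shUsp10-2. They lay so low in shNTC that a rise was needed to pass the filter on low values, so no share of them is given. Zscan4c was at 28.5 CPM ± 0.605 (SD, n = 3) against 0.883 CPM ± 0.233 in shNTC and 1.07 CPM ± 0.109 in shUsp10-1. Pramel39 was at 41.8 CPM ± 3.67 against 1.98 CPM ± 0.294, and Usp17lc at 18.7 CPM ± 0.715 against 1.95 CPM ± 0.360. These families hold near-identical copies that share reads, so the number of genes is uncertain.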
